A study of Homo sapiens with 6 samples.

How the data were processed

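Total RNA (1 µg) was extracted with Trizol and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. This kit, as generally known, selects polyadenylated RNA and does not mark strand. RNAs without a poly(A) tail, such as SCARNA13 and most histone transcripts, would therefore be poorly sampled. Some histone genes were nonetheless abundant, with HIST1H2BK at 379 FPKM and HIST1H1C at 281 FPKM on average in controls. Sequence reads were not used here. The deposited files give 1 FPKM value per gene and library, fragments scaled by gene length and library size, with the gene length, position and type beside it. TopHat2 2.0.9 and Bowtie2 2.0.6 with the hg19 build are named in the submitters' processing notes, with no role given. The counting tool, annotation and normalization are not given in the sources used here. The positions in the deposited files are those of GRCh38 and not hg19, since 56636 of 58039 gene identifiers found in GENCODE 29 (97.6%) had the same start and end there. Coordinates in the text are GRCh38.

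Each FPKM value multiplied by its gene length was a whole multiple of a single step per library, for 100% of values at a tolerance of 0.01 reads, so whole reads were recovered. They came to between 20457474 and 25173559 per library. The step implies library sizes of 30416028, 26628485 and 13089653 for the controls and 27150133, 28511472 and 15550655 for SCARNA13 ASO, which differ from the read totals. They equal the median-of-ratios size factor over the 6 libraries times the geometric mean of the totals. The deposited FPKM scale is therefore inferred, from the values and from no label, to assume that most genes do not change and to fix the median gene. No pair of libraries agreed within sampling noise (chi-square per gene of at least 3.16 over genes with 50 reads or more), so all were counted as separate. Intervals on reads are exact, at 95%, and cover counting error only.

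Groups and replicate numbers were taken from the sample titles. The test fixed before the data were examined was limma-trend on log2(FPKM + 0.5) for genes with a mean of at least 1 FPKM over the 6 libraries, with group as the only term and a Benjamini-Hochberg adjusted p under 0.05, two-sided. Fold changes are on that log2(FPKM + 0.5) scale, which understates the change of low genes. Replicate numbers were then checked as pairs. Deviations from the group means correlated across genes at 0.84, 0.78 and 0.91 for libraries of the same number. By the rule used here the numbers were therefore taken as pairs. Both crossed pairs of replicates 1 and 2 correlated at 0.81, so the values set apart only replicate 3. Deviations from a group mean cancel out, so a shared replicate 3 shift alone raises the correlations among replicates 1 and 2. Pairing 1 with 1 and 2 with 2 rests on the titles, with no label on shared cultures or days.

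A second fit was added after the data were seen. For each library, a loess trend (span 0.5) of the deviation from the mean over libraries was fitted on GC content and subtracted, and the replicate number entered limma-trend as a block. GC content came from the longest GENCODE 29 transcript of each gene, which left 10104 genes. Gene lists were tested with camera (preset correlation 0.01) when at least 5 members were tested, with an estimated correlation and with fry, adjusted over 27 lists. Targeted genes were also compared by exact two-sided permutation tests of 3 against 3 values, which cannot go below p = 0.1.

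Named genes followed a rule fixed beforehand: SCARNA13, SNHG10 and SOX9, the 12 largest rises and 12 largest falls among genes that passed, up to 4 members of each list with the smallest adjusted p, and the 5 most abundant genes that passed in each direction. Not every gene the rule selects is printed. Small RNAs, unnamed clones and pseudogenes were left out of the largest changes. As no gene passed in the first fit, the 12 smallest p-values were taken there, and the other parts of the rule were applied to the second fit, with the same direction in all 3 pairs in place of groups that do not overlap. The 31 lists covered hepatocyte, progenitor, epithelial, mesenchymal, cell cycle, p53, Wnt, YAP, TGF-beta, interferon, NF-kappaB, immediate early, stress, cholesterol, hypoxia, MYC, small RNA host, Cajal body, spliceosome, ribosome, mitochondrial, lysosome and histone genes, and markers of fibroblasts, endothelium and immune cells. A list of cytosolic aminoacyl-tRNA synthetase genes was added later.

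The fits were tested on simulated reads with 190 to 197 of the tested genes changed at random. Reads were drawn from the mean profile of each replicate number at the real library sizes. Both libraries of a number shared that profile, with no GC difference within a pair, so what the GC correction gains was not tested. The block without GC correction recovered 83.1% at 1.5-fold and 96.3% at 2-fold at a dispersion of 0.002. At a dispersion of 0.002, the fit without a block recovered 0% of genes changed 2-fold, and the GC-corrected fit with block recovered 19.8% at 1.3-fold, 81.5% at 1.5-fold and 96.3% at 2-fold. At a dispersion of 0.01 the latter recovered 0%, 38.5% and 96.8%. False calls made up 7.14% (3 of 42), 8.62% and 9.85% of its calls at the lower dispersion. At the higher they made up all 3 calls at 1.3-fold, 16.9% at 1.5-fold and 12.0% at 2-fold. These shares lie above the nominal level, but each setting was drawn only once. The 2 dispersions were set and not estimated from these libraries. Alternatives covered the pseudocount, the filter, the scaling, the trend, robust fitting, the block, a batch term for replicate 3, the loess span, limma-voom on recovered reads and each library or pair left out. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used.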

Results

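RNA sequencing was carried out on HCCLM3 cells, a human hepatocellular carcinoma line selected for its high metastatic capacity. The cells had been transfected with an antisense oligonucleotide (ASO), a short synthetic strand that pairs with a chosen RNA and is used to lower it. The Control ASO group and the SCARNA13 ASO group each held 3 libraries, and the comparison asked which genes respond when SCARNA13 is targeted. SCARNA13 belongs to the small Cajal body-specific RNAs, a class that guides the modification of spliceosomal RNAs. The control libraries held 25173559, 21864034 and 20663908 reads assigned to genes, and the SCARNA13 ASO libraries held 21975166, 23326235 and 20457474. Between 19362 and 22794 of the 58302 listed genes had a value above 0 in a library. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

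The targeted RNA was barely covered, and its level was lower in every SCARNA13 ASO library than in any control library. SCARNA13 (ENSG00000252481) lies on the minus strand of chromosome 14 at 95533355 to 95533629 on GRCh38, and its 275 bases sit within an intron of its host gene SNHG10. It averaged 0.652 FPKM ± 0.0852 (SD, n = 3) in controls and 0.373 FPKM ± 0.10 (SD, n = 3) after SCARNA13 ASO. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. These values rested on 6, 5 and 2 reads in the controls against 2, 3 and 2 reads, or 13 against 7 in all. The ratio of scaled reads was 0.53, with an exact 95% interval of 0.179 to 1.43 that covers counting error only, so a decrease was not resolved at this depth. Exons of GLRX5 on the opposite strand cover 127 of the 275 bases, and reads from a library kit that does not mark strand cannot be assigned to either gene there. GLRX5, named after its values were seen, measured 30.5 FPKM ± 2.61 in controls and 35.3 FPKM ± 3.90 after SCARNA13 ASO (SD, n = 3).

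The host transcript was measured with more reads. SNHG10 (ENSG00000247092), a long non-coding RNA gene at 95532297 to 95534872 on the same strand, has no exon that overlaps SCARNA13. It averaged 5.10 FPKM ± 1.10 in controls and 3.67 FPKM ± 0.681 after SCARNA13 ASO (SD, n = 3), from 657 against 491 reads. The ratio of scaled reads was 0.736, with an exact 95% interval of 0.653 to 0.829 for counting error. Control values were 4.43, 4.50 and 6.36 FPKM and treated values 3.05, 3.55 and 4.40 FPKM, lower in 3 of 3 replicate pairs. The exact permutation test of SNHG10 gave p = 0.1. Its log2 fold change was -0.42 ± 0.22 (SE, n = 3; limma-trend adjusted p = 1.0), and with GC correction and a replicate block it was -0.40 ± 0.077 (adjusted p = 0.0525). On deposited values with no block, the log2 fold change was -0.27 without Control ASO replicate 3 and -0.54 without SCARNA13 ASO replicate 3. Over all alternative settings the adjusted p of SNHG10 ran from 0.0243 to 1.0. GLRX5 exons cover 391 of its 1945 exonic bases.

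SOX9 (ENSG00000125398), a transcription factor of liver progenitor cells on chromosome 17 at 72121020 to 72126420, was lower in every treated library. It averaged 48.7 FPKM ± 0.629 in controls and 34.8 FPKM ± 1.19 after SCARNA13 ASO (SD, n = 3), which is 28.4% lower. The exact permutation test gave p = 0.1, again the smallest possible. With GC correction and a replicate block its log2 fold change was -0.45 ± 0.048 (limma adjusted p = 0.036), and without them the adjusted p was 1.0.

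**Figure D1:**
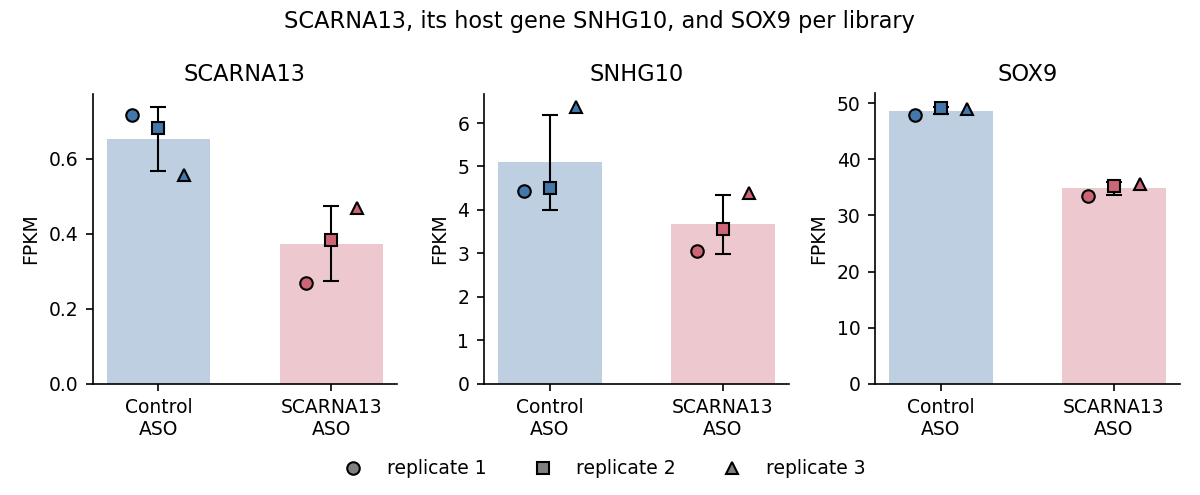
FPKM of SCARNA13, SNHG10 and SOX9 in each library, with bars for group means, error bars of 1 SD (n = 3) and symbols for the replicate numbers. SOX9 separates the groups, at 48.7 against 34.8 FPKM on average, while SCARNA13 averages below 1 FPKM in both.

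Among single genes, EPAS1, which encodes hypoxia-inducible factor 2 alpha, rose 2.15-fold, from 3.58 FPKM ± 0.530 to 8.02 FPKM ± 0.857 (SD, n = 3). LOX, the collagen cross-linking enzyme lysyl oxidase, rose 1.77-fold from 34.2 FPKM ± 2.19 to 62.3 FPKM ± 5.19, and FN1, encoding fibronectin, rose 1.73-fold from 5.93 FPKM ± 0.611 to 10.8 FPKM ± 1.90. SAT1, the enzyme that acetylates spermidine and spermine for polyamine breakdown, fell by 64.6%, from 25.8 FPKM ± 1.45 to 9.04 FPKM ± 2.06. ID2, an inhibitor of basic helix-loop-helix transcription factors, fell by 38.6%, from 4.83 FPKM ± 0.249 to 2.67 FPKM ± 0.230. Folds and calls here come from limma-trend on GC-corrected values with the replicate number as a block, a fit chosen after the data were seen.

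In that fit, 526 of 10104 genes passed an adjusted p of 0.05, of which 309 rose and 217 fell. At least a 1.5-fold change was seen for 84 of the genes that rose and 75 of those that fell, and a 2-fold change for 11 and 26. All 526 moved in the same direction in the 3 of 3 replicate pairs, and 446 were protein coding. The blocked fit selects genes whose change is alike in the pairs, so the shared direction is no separate support. The test fixed before the data were examined, limma-trend on the deposited scale with no block, called 0 of 10120 genes. There, 173 genes had an unadjusted p under 0.05 against 506 to be had by chance, and limma-voom on recovered reads also called 0 genes, with 228 at that unadjusted p. The replicate block without GC correction called 0 genes too, its smallest adjusted p being 0.0506, while 2598 genes had an unadjusted p under 0.05. The count of 526 became 14 without replicate 1 of both groups, and 0 without replicate 2, without the intensity trend or without a filter on low values.

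The libraries of replicate 3 stood apart from the rest in both groups. Log2 FPKM values correlated across genes at 0.900 to 0.939 between a replicate 3 library and any other number, and at 0.980 to 0.994 among the remaining pairs of libraries. Their deviation followed the GC content of the genes. In the highest decile of GC content, the median deviation from the mean of the 6 libraries was 1.05 on the log2 scale in the control library of replicate 3 and 0.76 in its SCARNA13 ASO counterpart, against -0.39 to -0.50 in the other 4 libraries. Within replicates 1 and 2 alone, on deposited values, 922 genes passed (457 rose and 465 fell), and 453 of them were among the 526. Replicate 3 was not used for those 922 calls, and its pair moved in the same direction for 863 of them, or 93.6%. For the 9198 genes that did not pass, that share was 65.3%.

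**Figure D2:**
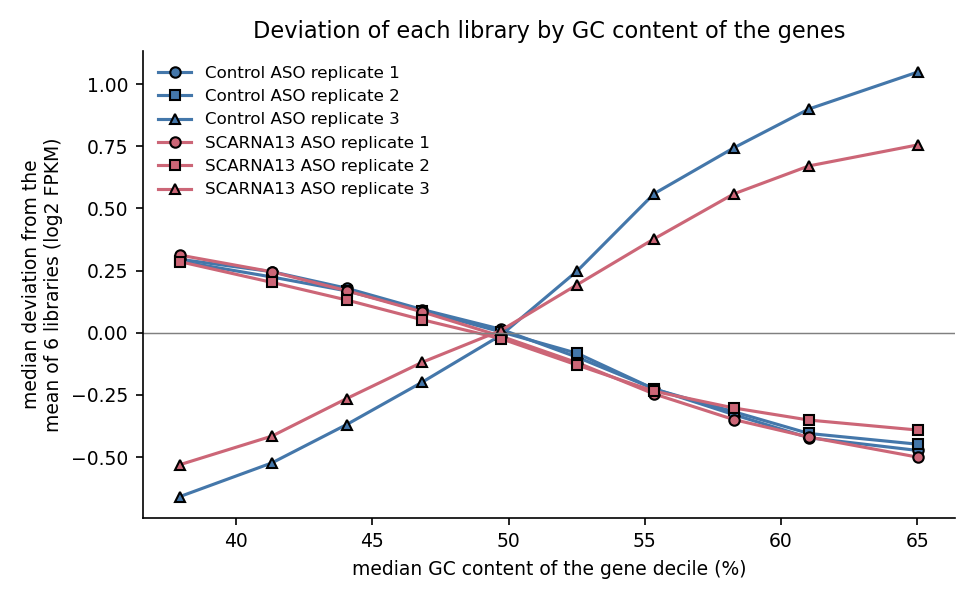
Median deviation of each library from the mean of the 6 libraries (log2 FPKM) in deciles of genes ordered by GC content (%), with 1 line per library. The replicate 3 libraries rise with GC content to 1.05 and 0.76, and the other 4 decline to between -0.39 and -0.50.

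The largest rises among annotated genes were led by LINC01775, a long non-coding RNA, at 1.35 ± 0.18 on the log2 scale (SE, n = 3), though its control level was only 0.614 FPKM ± 0.199. FOLR3, a folate receptor gene, followed at 1.23 ± 0.12, EPAS1 at 1.11 ± 0.067 and CBSL at 1.09 ± 0.19. CBSL is a near-identical copy of the cystathionine beta-synthase gene, so its reads could be shared with that copy. MMP24, a membrane-type matrix metalloproteinase, rose by 1.03 ± 0.057, and LY96, the partner of Toll-like receptor 4, by 1.02 ± 0.13. ATP5H, a subunit gene of ATP synthase, rose by 1.01 ± 0.12, SOWAHD by 0.99 ± 0.18 and the nuclear long non-coding RNA MALAT1 by 0.97 ± 0.061. The value of MALAT1 ran from 0.22 to 1.76 over all alternative settings, and its controls stood at 38.1, 38.2 and 7.28 FPKM. NNMT, which methylates nicotinamide, rose by 0.95 ± 0.062 from 37.0 FPKM ± 5.75 to 71.2 FPKM ± 17.1. DYSF, a membrane repair gene, and CUL9, a cullin, completed the 12 at 0.93 ± 0.099 and 0.90 ± 0.14. Adjusted p-values of these 12 genes lay between 0.0241 and 0.0487 in limma.

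The largest falls began with the histone gene HIST1H3B at -2.72 ± 0.22 on the log2 scale (SE, n = 3), SAT1 at -1.50 ± 0.18 and the antisense transcript MAN1B1-AS1 at -1.42 ± 0.22. HIST1H2AE followed at -1.36 ± 0.068 and HIST1H1C, a linker histone gene, at -1.01 ± 0.16. ANGPTL4, a secreted inhibitor of lipoprotein lipase, fell by 56.0% and the hair keratin KRT81 by 56.0%. The interferon-inducible OASL fell by 54.8%, the cation channel TRPV2 by 52.2% and HES1, a Notch target repressor, by 50.2%. The non-coding SNHG21 fell by 52.0% and LINC01003 by 50.1%. Adjusted p-values of these 12 genes lay between 0.0241 and 0.0492 in limma. MAN1B1-AS1 and SNHG21 are annotated as antisense to other genes, from which their reads cannot be told apart without strand, and histone genes share sequence with their copies.

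**Figure D3:**
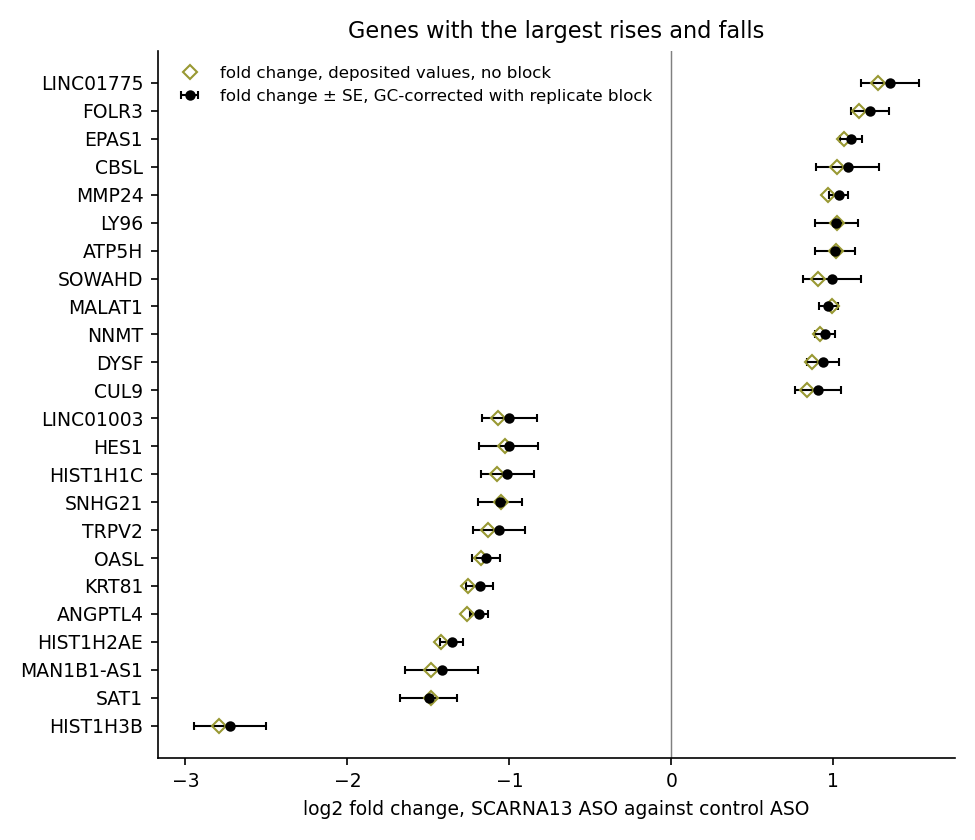
Log2 fold changes (SCARNA13 ASO against control ASO) of the 12 largest rises and 12 largest falls. Filled points with bars of 1 SE (n = 3) come from the GC-corrected fit with replicate block. Open diamonds come from deposited values with no block, with EPAS1 at 1.11 and 1.07. The block does not change a fold in this balanced design, so the 2 sets of points differ only by the GC correction. The SE without block, not drawn, was 0.18 for EPAS1, 0.90 for MALAT1 and 0.93 for HIST1H3B.

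Among the most abundant genes that passed, IGFBP6 rose 1.35-fold, the chaperone gene CALR 1.31-fold and the stress cytokine gene GDF15 1.24-fold. On the falling side, SNHG19 fell by 49.3%, HIST1H2BK by 47.7%, CDC20 by 27.6%, the metallothionein MT2A by 27.1% and TAGLN2 by 26.0%. In fits of deposited values with no block that left out 1 library, log2 fold changes turned to -0.32 at the lowest for GDF15, 0.15 for CDC20 and 0.029 for TAGLN2. Over all alternative settings, MT2A ran from -0.95 to -0.00055 and IGFBP6 from 0.021 to 0.77. The smallest unadjusted p-values of the fit fixed beforehand belonged to SAT1 (0.000657), EPAS1 (0.00102), LINC01775, ID2, SNHG21, LINC01003, LINC00857, SOWAHD, PIGW, DYSF, FN1 and LOX. Of these, PIGW, a gene of glycolipid anchor synthesis, did not pass with GC correction and block (-0.73 ± 0.14, adjusted p = 0.0532), and LINC00857 fell by 40.9%.

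Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01. On GC-corrected values with the block, 13 of 27 testable lists passed an adjusted p of 0.05. None of them passed with an estimated correlation, where the smallest adjusted p was 0.410. That form of camera has little power with so few libraries, whatever the correlation. For the integrated stress response (ATF4) list the estimate was -0.011, below the preset, yet unadjusted camera p went from 2.17e-06 to 0.0369. Failing it is therefore no evidence by itself that correlation between members made a result. The fit fixed beforehand called 9 of those 13 lists by camera, and 0 with an estimated correlation. The lists it did not call were the progenitor (adjusted p = 0.0604), NF-kappaB (0.194), MYC (0.209) and cytosolic ribosomal (0.193) lists. In each account below, members are counted after adjustment over all genes tested, and then adjusted over the list alone.

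Genes of the integrated stress response, driven by the transcription factor ATF4, gave the highest list median, at 0.44 on the log2 scale (camera adjusted p = 2.92e-05, and adjusted p = 0.410 with an estimated correlation). Of 15 members, 8 rose, 0 fell and 7 did not pass, with 11 rising adjusted over the list alone. DDIT3, encoding the stress factor CHOP, rose 1.52-fold from 19.7 FPKM ± 4.29 to 30.0 FPKM ± 7.97 (SD, n = 3). PPP1R15A, which restores translation after stress, rose 1.45-fold, the secreted STC2 1.44-fold and SESN2 1.36-fold. On deposited values with no block and without SCARNA13 ASO replicate 3, PPP1R15A stood at -0.053 and SESN2 at -0.22. The list median was 0.47 in replicates 1 and 2 and 0.39 in replicate 3. Unfolded protein response genes had a median of 0.15 (camera adjusted p = 0.0113, and adjusted p = 0.410 with an estimated correlation). Of 15 members, 2 rose, 0 fell and 13 did not pass, with 3 rising adjusted over the list alone. HSPA5, the main chaperone of the endoplasmic reticulum, rose 1.34-fold from 66.5 FPKM ± 4.88 to 89.8 FPKM ± 9.50, and CALR also rose. XBP1 stood at 0.21 ± 0.048 and SEL1L at 0.26 ± 0.083 without passing.

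Mesenchymal genes had a median of 0.17 (camera adjusted p = 0.0113, and adjusted p = 0.410 with an estimated correlation). Of 13 members, 4 rose and 9 did not pass, with 4 rising adjusted over the list alone. They included LOX, FN1 and SNAI2, a transcription factor of the epithelial to mesenchymal transition that rose 1.67-fold from 6.72 FPKM ± 1.99 to 11.4 FPKM ± 1.2 (SD, n = 3). Epithelial genes showed no list call (camera adjusted p = 0.524), and 0 of 6 members passed, with 1 rising adjusted over the list alone. KRT19 stood at 0.25 ± 0.057, CLDN1 at 0.26 ± 0.080, KRT18 at -0.21 ± 0.082 and CLDN7 at 0.13 ± 0.067.

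The list of G1/S and DNA replication genes had a median of -0.20 (camera adjusted p = 0.000182, and adjusted p = 0.410 with an estimated correlation). Of 19 members, 4 fell, 0 rose and 15 did not pass, with 9 falling adjusted over the list alone. CCNE1, the cyclin of entry into S phase, fell by 28.3% from 6.31 FPKM ± 0.30 to 4.24 FPKM ± 0.197 (SD, n = 3), the licensing factor CDT1 by 26.1%, the flap endonuclease FEN1 by 20.8% and the sliding clamp PCNA by 17.5%. Genes of G2/M and mitosis had a median of -0.25 (camera adjusted p = 2.73e-05, and adjusted p = 0.410 with an estimated correlation). Of 21 members, 4 fell, 0 rose and 17 did not pass, with 14 falling adjusted over the list alone. They were CDC20, the mitotic kinesin KIF20A, which fell by 21.8%, BIRC5, which fell by 20.0%, and the kinase PLK1, which fell by 18.0%. On deposited values with no block and without Control ASO replicate 3, CDT1 stood at 0.26, CDC20 at 0.15 and PLK1 at 0.18. Replicate 3 gave medians of -0.15 and -0.28 for these lists, against -0.23 in both from replicates 1 and 2.

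Replication-dependent histone genes had the lowest list median, -0.75 (camera adjusted p = 0.0140, and adjusted p = 0.446 with an estimated correlation). Of 11 members, 4 fell, 0 rose and 7 did not pass; adjusted over the list alone, 5 fell and 1 rose. Besides HIST1H2AE, HIST1H1C and HIST1H2BK, HIST2H2BE fell by 45.2%. The median was -0.50 in replicates 1 and 2 and -1.04 in replicate 3. Mitochondrially encoded genes had a median of -0.33 (camera adjusted p = 0.00155, and adjusted p = 0.554 with an estimated correlation), with 0 of 13 members passing and 3 falling adjusted over the list alone. The estimated correlation was 0.90, far above the preset of 0.01, so the preset camera p-value treats these members as more independent than they were. Here too the replicates differed, with -0.17 in replicates 1 and 2 and -0.64 in replicate 3. MT-ND2 stood at -0.56 ± 0.12, MT-ND1 at -0.56 ± 0.13, MT-ND5 at -0.49 ± 0.11 and MT-ND4L at -0.38 ± 0.13. All mitochondrial transcripts, rRNA included, took 7.16%, 6.70% and 5.18% of the reads in controls and 6.37%, 6.01% and 4.62% after SCARNA13 ASO, in the order of the replicate numbers. Mitochondrial mRNAs alone took 6.44%, 6.02% and 4.10% against 5.62%, 5.26% and 3.33%. The library size implied by the FPKM step was 0.633 of the read total in Control ASO 3 and 0.760 in SCARNA13 ASO 3. The size of the fall in replicate 3 therefore depends in part on that scaling.

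Heat shock genes had a median of -0.24 (camera adjusted p = 0.000641, and adjusted p = 0.410 with an estimated correlation). Of 10 members, 4 fell and 6 did not pass, with 6 falling adjusted over the list alone. The co-chaperone gene BAG3 fell by 28.8%, HSPA1A by 25.6%, HSPA1B by 23.6% and HSPA8 by 18.6%, though reads of HSPA1A and HSPA1B could be exchanged between these near-identical genes. Targets of TGF-beta signalling had a median of -0.31 (camera adjusted p = 0.00279, and adjusted p = 0.410 with an estimated correlation) with members on both sides. Of 10 members, 1 rose, 1 fell (ID2) and 8 did not pass, among them SMAD7 at -0.68 ± 0.14 and SMURF1 at -0.37 ± 0.071. Adjusted over the list alone, 7 fell and 1 rose. Hepatic progenitor and liver cancer stem cell genes had a median of -0.29 (camera adjusted p = 0.0398, and adjusted p = 0.410 with an estimated correlation). SOX9 was the 1 of 6 members that fell, and CD44 (-0.33 ± 0.061, adjusted p = 0.0504), KRT19 and ANPEP (-0.24 ± 0.058) did not pass. Adjusted over the list alone, 4 fell and 1 rose.

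NF-kappaB target genes had a median of -0.22 (camera adjusted p = 0.0377, and adjusted p = 0.410 with an estimated correlation), with 0 of 12 members passing. Adjusted over the list alone, 4 fell and 1 rose, with NFKBIA at -0.44 ± 0.10, IER3 at -0.42 ± 0.079, NFKB2 at -0.24 ± 0.052 and CXCL2 at 0.42 ± 0.12. MYC target and ribosome biogenesis genes had a median of -0.12 (camera adjusted p = 0.0366, and adjusted p = 0.410 with an estimated correlation), yet the 1 member of 14 that passed, NPM1, rose 1.3-fold. Adjusted over the list alone, 4 fell and 1 rose. NOP2, RRS1 and NOP16 stood at -0.21 ± 0.047, -0.26 ± 0.058 and -0.22 ± 0.058. Cytosolic ribosomal protein genes had a median of -0.16 (camera adjusted p = 0.00967, and adjusted p = 0.617 with an estimated correlation). Their estimated correlation was 0.68, again far above the preset of 0.01. Of 25 members, 1 rose, 0 fell and 24 did not pass, with the same counts adjusted over the list alone. RPL7A stood at -0.32 ± 0.10, RPLP2 at -0.26 ± 0.085 and RPL4 at -0.18 ± 0.061. The list median was -0.06 in replicates 1 and 2, where camera without a block gave adjusted p = 0.0575 and with it 0.0440, and -0.32 in replicate 3.

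**Figure D4:**
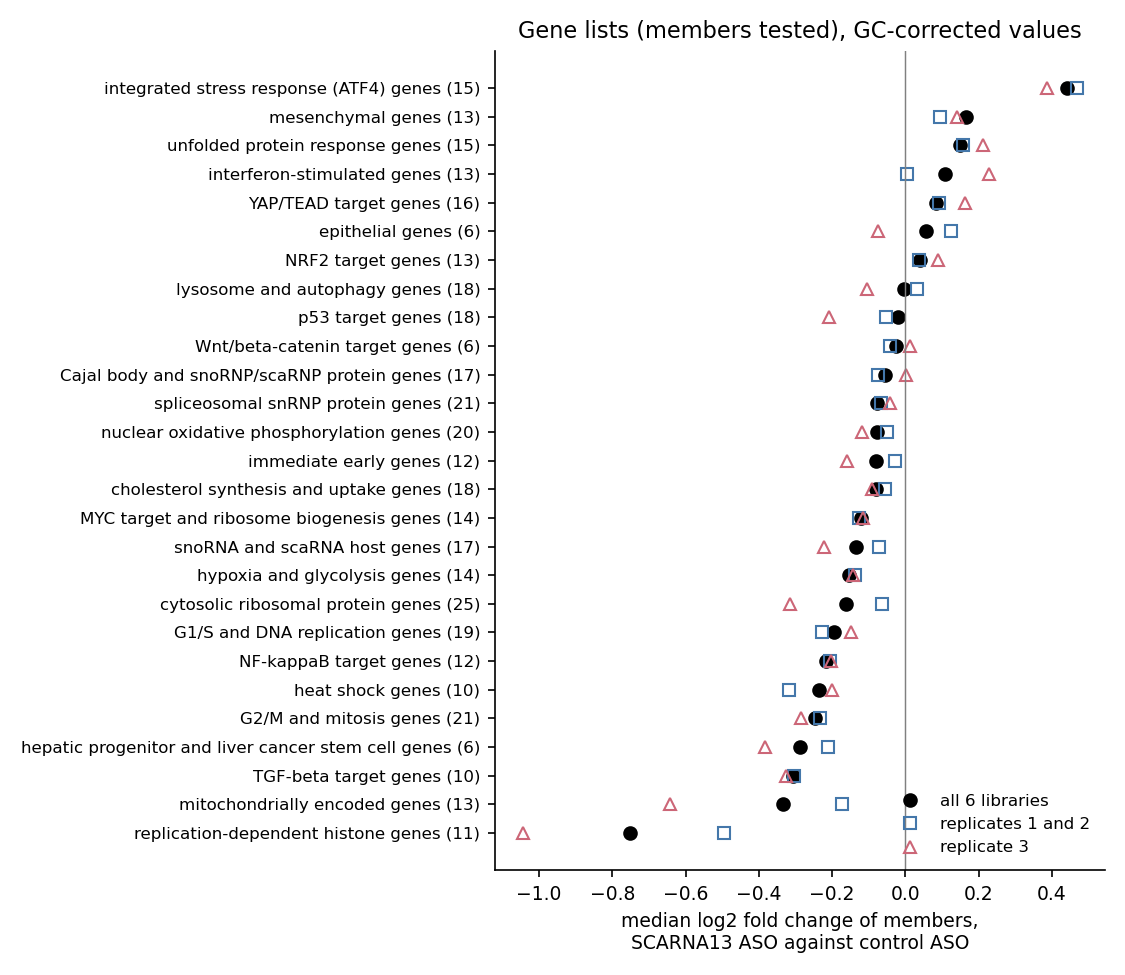
Median log2 fold change (SCARNA13 ASO against control ASO) of the tested members of each gene list, with the number tested in brackets, for all 6 libraries, for replicates 1 and 2, and for replicate 3. ATF4 genes lie highest at 0.44 and histone genes lowest at -0.75 over the 6 libraries.

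Lists tied to the function of SCARNA13 gave no camera call on GC-corrected values with the block. Hosts of small nucleolar and Cajal body RNAs had a median of -0.13 (adjusted p = 0.0899, and 0.0332 without replicate 1), with SNHG1 falling by 34.3% as the 1 of 17 members that passed. SNHG3 stood at -0.88 ± 0.17 (adjusted p = 0.0525), SNHG4 at -0.53 ± 0.12 and SNHG8 at 0.32 ± 0.068, and 3 fell and 1 rose adjusted over the list alone. Protein genes of Cajal bodies and their RNPs had a median of -0.06 (adjusted p = 0.192). GEMIN4, a component of the SMN complex, fell by 27.6% as the 1 of 17 members that passed under either adjustment. WRAP53 stood at -0.37 ± 0.089, COIL at -0.28 ± 0.12 and NOLC1 at -0.12 ± 0.048. Spliceosomal snRNP protein genes had a median of -0.08 (adjusted p = 0.0585, and 0.0293 in replicates 1 and 2). Of 21 members 3 fell, and 6 fell adjusted over the list alone. These were SF3A1 (24.0% lower), SF3A2 (23.7% lower, but at 0.15 on deposited values with no block and without Control ASO replicate 3) and SF3B2 (20.4% lower), while PRPF8 stood at -0.19 ± 0.046.

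The remaining lists gave no camera call on GC-corrected values with the block. YAP/TEAD targets had a median of 0.08 (adjusted p = 0.0551, 0.0484 with the block alone and 0.0345 in replicates 1 and 2), where CTGF, a matricellular protein gene, fell by 32.5% and GADD45A rose 1.44-fold among 16 members, with 7 rising and 2 falling adjusted over the list alone. FSTL1 stood at 0.51 ± 0.099 and AXL at 0.30 ± 0.060. Of 18 p53 targets, DDB2 fell by 28.0% and GDF15 rose (median -0.02, adjusted p = 0.126), FDXR stood at -0.35 ± 0.067 and PLK3 at -0.22 ± 0.050, and 6 fell and 1 rose adjusted over the list alone. Of 13 interferon-stimulated genes, OASL and ISG15 fell (camera adjusted p = 0.937 for the list). ISG15 fell by 44.6%, and its log2 fold change ran from -1.49 to -0.13 over all alternative settings. The interferon list had a median of 0.11 and a mean of -0.07, both passing genes fell under either adjustment, and IFI6 and IFIT1 stood at 0.17 ± 0.049 and 0.34 ± 0.12. Of 12 immediate early genes, IER2 fell by 23.0%, though it stood at 0.10 without Control ASO replicate 3 on deposited values with no block (median -0.08, adjusted p = 0.425), JUNB stood at -0.70 ± 0.17, NR4A1 at -0.38 ± 0.097 and DUSP1 at 0.31 ± 0.060, and 4 fell and 2 rose adjusted over the list alone. Of 13 NRF2 targets, the cystine transporter gene SLC7A11 rose 1.45-fold under either adjustment (median 0.04, adjusted p = 0.229), with SRXN1 at 0.44 ± 0.14, TALDO1 at 0.18 ± 0.047 and TXN at 0.18 ± 0.058.

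Of 14 hypoxia and glycolysis genes, LDHA, the lactate dehydrogenase A gene, fell by 20.6% (median -0.15, adjusted p = 0.137, and 0.0487 in replicates 1 and 2), and 3 fell and 2 rose adjusted over the list alone. PFKFB3 stood at -0.28 ± 0.059, NDRG1 at 0.36 ± 0.080 and HK2 at 0.25 ± 0.061. Of 20 nuclear oxidative phosphorylation genes, NDUFV1 of complex I rose 1.37-fold under either adjustment, though it stood at -0.073 without SCARNA13 ASO replicate 3 on deposited values with no block (median -0.08, adjusted p = 0.636), with UQCRC1 at -0.21 ± 0.051, ATP5A1 at -0.20 ± 0.055 and COX7C at 0.16 ± 0.053. Of 18 lysosome and autophagy genes, the protease gene CTSL and WIPI1 rose 1.3-fold and 1.29-fold (median -0.00, adjusted p = 0.984). MCOLN1 stood at -0.37 ± 0.070 and GLA at -0.30 ± 0.064, and 3 fell and 2 rose adjusted over the list alone. None of 18 cholesterol synthesis and uptake genes passed (median -0.08, adjusted p = 0.411), with 2 rising and 1 falling adjusted over the list alone, LSS at 0.39 ± 0.076, FDPS at 0.21 ± 0.049 and MVD at 0.25 ± 0.076. None of 6 Wnt/beta-catenin targets passed (median -0.03, adjusted p = 0.984), with 1 rising adjusted over the list alone, DKK1 at 0.25 ± 0.057, CCND1 at -0.15 ± 0.047, MYC at 0.09 ± 0.059 and TBX3 at -0.15 ± 0.10.

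Markers of hepatocytes and of other cell types were mostly below the level tested. Of 21 hepatocyte genes, 19 averaged under 1 FPKM, and the 2 above it, SERPINA1 and CEBPA, did not pass at -0.15 ± 0.081 and -0.34 ± 0.14. Of 9 fibroblast markers only COL3A1 was tested (0.26 ± 0.069, not passing), with 1 rising adjusted over the list alone. All 10 endothelial markers averaged under 1 FPKM, the highest being ESAM. Of 12 immune cell markers, CD74 and CD14 were tested and did not pass (-0.14 ± 0.052 and -0.65 ± 0.13), with 2 falling adjusted over the list alone.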

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

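No gene passed in the unblocked fit fixed beforehand under any pseudocount, filter, scaling or trend, with any library left out, or with GC correction alone. Its count of 0 became 526 with GC correction and replicate block, 873 with a batch term for replicate 3, 1712 with both GC correction and that term, 922 in replicates 1 and 2 alone, and 900 by voom with replicate block. The replicate block without GC correction left it at 0. The count of 526 became 0 without a filter, 1012 at a mean of at least 5 FPKM (5227 genes tested), 1290 after quantile normalization, 0 without the trend, 159 at 1.5-fold or more by construction, 1712 with the batch term in place of the block, 0 without the block, 0 without GC correction, and 900 by voom with block. With 1 replicate pair left out it ran from 0 to 763. Apart from the smaller numbers of genes or samples, the cause was not tested. It was 562 and 444 at pseudocounts of 0.1 and 1, 524 with robust fitting, 526 after median scaling and 522 and 532 at other loess spans. SCARNA13 never passed, at -0.27 to -0.69. SNHG10 passed only with the batch term, at -0.42 (adjusted p = 0.0326) and, GC-corrected, -0.40 (adjusted p = 0.0243). The 9 lists called by camera beforehand became 0 with an estimated correlation and 0 by fry, 4 to 8 with a library left out, and 13 with the block. The 13 called with GC correction and block became 0 with an estimated correlation, while fry called 8 lists, among them NRF2 targets, which camera had not called. With 1 replicate pair left out, camera called 10 to 15. Of 138 named genes, 73 passed with GC correction and block. With 1 change at a time to that limma-trend fit, none of those 73 passed without the filter, the trend, the block, GC correction or replicate 2. Without replicate 1, 67 were lost, and without replicate 3, 2 were lost. Without GC correction, only 3 were lost with a batch term for replicate 3 in place of the block. Voom with replicate block, also uncorrected, lost 8. In uncorrected, unblocked fits with a library left out, 10 of the 73 changed sign when replicate 3 of a group was dropped. From lowest to highest, these were GDF15 (-0.32 to 0.91, with -0.11 and -0.085 without Control ASO 1 or 2), TAGLN2 (-0.91 to 0.029), CDC20 (-1.05 to 0.15), CDT1 (-1.09 to 0.26), PLK1 (-0.79 to 0.18), IER2 (-0.90 to 0.10), SF3A2 (-0.96 to 0.15), PPP1R15A (-0.053 to 1.03), SESN2 (-0.22 to 1.07) and NDUFV1 (-0.073 to 0.89). Those fits weigh replicate 3 unequally between the groups. SCARNA13 had 20 reads in all, which limits any statement on its level.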

Other observations

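The small RNAs below were chosen only after their values were seen. Among 39 small nucleolar RNAs tested with GC correction and block, 6 fell and 0 rose, with a median of -0.46. SNORA60 fell most, at -3.39 ± 0.33 on the log2 scale (SE, n = 3; adjusted p = 0.036), from 39, 44 and 30 reads in controls to 5, 2 and 1. SNORA65 (75 against 22 reads), SNORA5C (369 against 135), SNORD14A (26 against 8), SNORA71B (44 against 12) and SNORD12C (12 against 4) also fell. SCARNA7, the only small Cajal body-specific RNA tested, rose by 1.26 ± 0.14 (22 against 84 reads). None of these RNAs carries a poly(A) tail, as generally known, so their counts are small and depend on carry-over.

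The list of cytosolic aminoacyl-tRNA synthetase genes was added after the ATF4 result. Of 12 members, 4 rose, 0 fell and 8 did not pass, with 10 rising adjusted over the list alone. AARS, WARS, IARS and MARS rose by 0.49 ± 0.056, 0.45 ± 0.080, 0.38 ± 0.068 and 0.36 ± 0.061 on the log2 scale (SE, n = 3), and NARS stood at -0.09 ± 0.067. The median was 0.343, with a camera p of 5.69e-06 and p = 0.168 with an estimated correlation.

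The tests of GC content, of immediate early genes and of carry-over were written only after the results were seen. The replicate 3 libraries stood apart in both groups, and a trend on GC content took up 64.8% and 65.5% of the variance of their shift. Gene length took up 2.39% at most of what was left, which argues against a length bias beyond GC content. Length was not fitted before the GC correction, so a part shared with GC content was not tested. Immediate early genes, at the 78.4 percentile of 10000 matched random lists, could not tell whether the cells were also in another state. A bias tied to GC content would be consistent with part of the shift, but after GC correction replicate 3 still correlated at 0.95 to 0.972 with the other numbers, against 0.977 to 0.994 among the rest, and what remained of the shift correlated at 0.758 between the groups, so its cause stays open.

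Lower histone transcripts might come from less carry-over of RNA without a poly(A) tail or from fewer cells in S phase. Abundant RNAs taken to lack a tail had a median change of 0.0608, against -0.753 for the histone genes. These were only 4 RNAs, from mitochondrial rRNA and 7SL genes, and whether each lacks a tail was not examined. Classes generally without a tail had medians on both sides, at -0.46 for small nucleolar RNAs (6 of 39 fell, 0 rose), -0.55 for small nuclear RNAs (0 of 15 passed), -0.67 for mitochondrial tRNAs (2 of 16 fell, 0 rose) and 0.77 for rRNA genes (2 of 8 rose, 0 fell), so less carry-over was neither shown nor excluded. The G1/S genes had a median of -0.195 (camera adjusted p = 0.000182), which fewer cells in S phase could give. Camera with an estimated correlation gave adjusted p = 0.410, but that form has little power here. The explanation stays open.

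The rise of ATF4 genes may reflect ATF4 activity, since the synthetase genes, also ATF4 targets, had a median of 0.343. On GC-corrected values the list stood at the 100 percentile of 10000 random lists matched on level and GC content. A trend on level, or a GC trend left after the correction, would therefore not account for its median. The ATF4 targets ASNS (-0.17), CTH (-0.14) and SLC3A2 (-0.02) did not pass. The labels do not say how many SCARNA13 ASOs were used, and effects of the oligonucleotide apart from its target could not be told from effects of SCARNA13.

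All 10 splits of the 6 libraries into 3 and 3 gave 0 genes in the fit fixed beforehand, so 10 of 10 reached the real count. Unadjusted p-values under 0.05 numbered 1438 to 2459 in the 4 splits that put both replicate 3 libraries on the same side, against 173 for the real groups. With GC correction and block, 1 of 10 splits, the real grouping itself, reached 526, and the other splits gave 0. Only 4 splits part all 3 replicate pairs, the real grouping among them, so the fitting comparison for the block is 1 of 4. There are too few splits for a share under 0.05.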
